A study of Ovis aries with 16 samples.

How the data were processed

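RNA sequencing libraries from liver and skeletal muscle (vastus lateralis) of 8 female Suffolk sheep were compared, 4 prenatally exposed to bisphenol A (BPA) and 4 controls, with both tissues from each animal, giving 16 libraries. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with a low-input kit. Per the submitters' processing notes, Trimmomatic, FastQC and DESeq2 1.24.0 were used. The aligner, the read counter, the gene annotation and the genome build are not given in the sources used here, and neither is strandedness of the counting, so genes with near-identical copies and overlapping antisense genes stay uncertain.

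The deposited table holds a normalized signal per gene, read counts divided by 1 size factor per library, over all 16 libraries together. Each column consisted of whole multiples of 1 step, so whole reads were recovered by dividing by that step: within a tolerance of 0.1 read, at least 99.996% of the values in every library came out whole. In units of 1e6 (M), recovered totals ranged from 4.39 to 19.28 M reads in liver and from 15.15 to 28.54 M in muscle. The table had 28524 rows, of which 3425 were at 0 in every library. Of the names, 22250 were found in the RefSeq gene table of assembly ARS-UI_Ramb_v3.0, used for names and neighbouring genes only. Of 10441 names made of LOC and a number, 6969 were found there by gene number and 406 were given a current symbol. No column of values was left unused.

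Each tissue was tested alone with limma 3.58.1 (R 4.3.3) on log2(value + 1), for genes with a mean of at least 10 over the tissue's 8 libraries, with eBayes and an intensity trend and Benjamini-Hochberg (BH) adjustment over all genes tested. Fold changes are on this scale, which understates changes of low genes. The threshold was an adjusted p of 0.05. A 4-group fit over the 16 libraries tested liver against muscle (mean of at least 10 over all libraries) and the difference between the BPA effects in the 2 tissues (mean of at least 10 in each). Counts per gene as whole reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. All p-values quoted as adjusted come from limma unless another tool is named.

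Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusting over the lists with at least 5 tested members. The 49 lists (metabolic pathways, stress and immune responses, organelles, and cell-type markers), the panels of single genes, the designs and most alternatives were fixed before the data were examined. Genes named in a comparison were those past the threshold whose 4 BPA libraries all lay above or below the 4 controls (up to 10 per direction, symbols only). Directions with fewer than 5 were filled to 5 by smallest p. Added to these were the 3 members with the smallest p of each list past the threshold, the 5 smallest p per direction of the difference between tissues, and the panels. Genes named outside this rule are said to have been chosen later, and a few genes that the rule selects are not reported here.

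The same sheep number in liver and muscle marks the same animal, per the labels, so the 2 tissues are paired. An animal's deviations from its group means correlated between its liver and its muscle, across genes, by -0.10 to 0.12. The highest correlation of each liver with the muscle of another animal was 0.09 to 0.17. The expression values thus do not bear out the pairing by themselves, and it rests on the labels. With the animal as a block, 11091 genes passed between tissues and 0 for the difference between BPA effects. Within a tissue each animal belongs to 1 group, so no block applies to liver or muscle alone.

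The alternatives were other pseudocounts, filters and scalings, robust and weighted fits, the count tests, and leaving out each library or animal. Splits of the 8 animals into 4 and 4 (35, the real one included) and 100 seeded splits of the 16 libraries were refitted. The pipeline was tested on simulated data with the real means, depths and spread and 200 changed genes. For muscle BPA against control (14560 genes), limma recovered 72.4% of genes changed 2-fold and 95.9% changed 4-fold. For liver (15391 genes) it recovered 0% at 2-fold, 14.1% at 4-fold and 84.1% at 16-fold. In simulated liver DESeq2 wrongly called 45 genes and limma and edgeR 4 each, and in muscle DESeq2 24, edgeR 4 and limma 2. For the difference between BPA effects (13470 genes) limma recovered 0% at 2-fold and 31.6% at 4-fold (0% and 0% with the animal as a block), and for liver against muscle (15800 genes) 36.7% and 83.7%. Of 5 lists with every member doubled, camera and fry recovered all 5 in each tissue, with 1 other list called by camera in muscle. The genes were simulated independently of one another, whereas members of a real list were correlated (estimated 0.92 for cytosolic ribosomal proteins in liver). The simulation therefore says nothing about false calls at the preset correlation. It also held no differences between libraries shared by many genes, which the real livers had. Its wrong calls and recovery of single genes therefore need not hold for these livers. Lists of mitochondrially encoded transcripts and of long nuclear and structural RNAs had 0 members in the table and were not analysed here, nor were the panel genes CYP7A1, CD36 and MYH7.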

Results

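Liver (tip of the left lobe) and vastus lateralis muscle were collected from female sheep whose mothers had received BPA, a plasticizer with oestrogen-like activity, or corn oil. Mothers were injected subcutaneously with 0.5 mg/kg BPA daily from day 30 to day 90 of gestation. The offspring were sampled at about 21 months of age, after a 48 hour fast, in the late follicular phase of a synchronized cycle. The study asked how prenatal BPA changed the liver and muscle transcriptomes. Each of the 4 groups held 4 libraries, each from a separate animal. Control liver libraries held 4.39 to 19.28 M recovered reads and BPA liver libraries 4.66 to 17.92 M. Control muscle libraries held 16.16 to 28.54 M and BPA muscle libraries 15.15 to 26.54 M. Reads in M are in units of 1e6. Values are normalized read counts, given as mean ± SD with n = 4 unless stated.

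Liver and muscle differed in the genes that define them. ALB, which encodes serum albumin, measured 384900 ± 310400 in liver and 4482 ± 1596 in muscle (SD, n = 8 each), a log2 difference of 5.64 (SE 0.737). The apolipoprotein gene APOA1 (5.99), the transthyretin gene TTR (5.76) and CYP2E1, a cytochrome P450 (6.37), were likewise higher in liver on the log2 scale. Muscle creatine kinase CKM measured 7.92 ± 12.5 in liver and 363700 ± 30870 in muscle. Skeletal actin ACTA1 (log2 difference -16.95) and the fast myosin light chain gene MYLPF (-15.08) were also lower in liver. All 7 passed, with adjusted p between 2.43e-13 and 5.36e-06. Of 15995 genes tested with limma, 11420 passed, 5780 higher in liver and 5640 higher in muscle.

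The liver libraries differed from one another along cell-type and housekeeping lists more than by group. The control liver 902 (4.39 M reads) had ALB at 10450 against 677300 to 739600 in the other controls, and the collagen gene COL1A1 at 43400 against 1046 to 1956. These 2 genes were looked at after their values were seen. Its median hepatocyte marker lay at -2.84 log2 units from the mean of the 8 liver libraries, and its fibroblast and stellate markers at 1.22. The BPA livers 918, 977 and 984 (4.66, 7.27 and 10.64 M reads) had cytosolic ribosomal protein medians of -1.55, -1.67 and -2.06, and hepatocyte medians of -0.31, -0.71 and -0.79. The BPA liver 910 (17.92 M reads) had a ribosomal protein median of 1.25 and a hepatocyte median of 1.31, with the controls 908, 924 and 928 at 1.28 to 1.41 and 1.21 to 1.34. Its mean correlation with those 3 controls was 0.973, compared with 0.694 for the control 902.

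**Figure D1:**
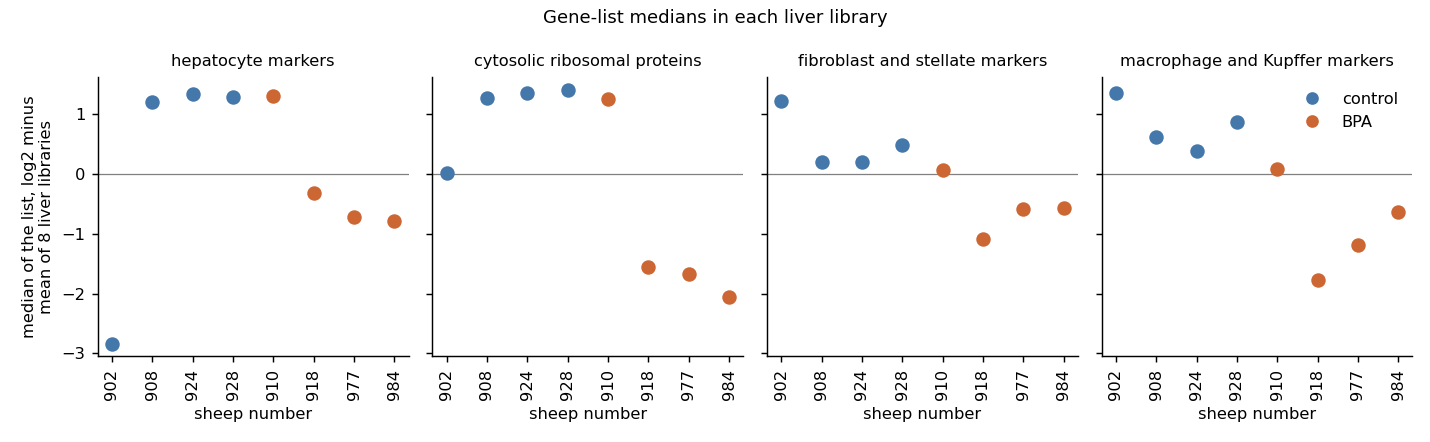
Median log2 level of 4 gene lists in each liver library (y axis, log2 units from the mean of the 8 liver libraries, 1 point per library, sheep number on the x axis, blue control and orange BPA). The BPA library 910 lies near the controls 908, 924 and 928 for hepatocyte markers (1.31) and ribosomal proteins (1.25), and the control 902 lies at -2.84 for hepatocyte markers.

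In liver, prenatal BPA gave no gene past the threshold of limma, and the largest differences were as follows. The genes with the smallest p among those higher in BPA were MAP2, a microtubule-associated protein gene (150 ± 84.7 in controls and 797 ± 297 in BPA), ENO4, an enolase (71.0 ± 24.5 and 448 ± 250), and AFMID, an enzyme of tryptophan breakdown (694 ± 119 and 2341 ± 781). KCNT2, a potassium channel, measured 117 ± 24.6 and 274 ± 45.3, and PGLYRP1, a peptidoglycan recognition protein, 9.33 ± 2.04 and 45.0 ± 22.1. Those lower in BPA were CDA, the cytidine deaminase gene (413 ± 77.0 and 124 ± 18.1), LYVE1, a receptor of lymphatic and sinusoidal endothelium (519 ± 159 and 88.8 ± 53.8), and COPS9, a signalosome subunit (150 ± 53.9 and 33.5 ± 7.07). CDKN1A, a cell-cycle inhibitor, measured 362 ± 113 in controls and 91.3 ± 37.0 in BPA, and the prostaglandin transporter SLCO2A1 1384 ± 697 and 298 ± 59.2. All 10 had an adjusted p of 0.256, and in each the 4 BPA livers lay entirely above or below the 4 controls. Of 15689 genes tested, 0 passed with limma and 0 with edgeR, while DESeq2 called 190, 137 of them higher. With sample quality weights limma called 9588, and with all 16 libraries in one fit 2299. At an unadjusted p under 0.05 there were 2838 genes (limma) against 784 from chance, and 1194 genes (7.6%) had groups that did not overlap, against 2.9% by chance. Without the BPA liver 910, limma called 2595 genes (1155 higher, 1440 lower), all 10 named here among them. With the depth class (over or under 15 M reads) as a covariate it called 0, with 2671 at an unadjusted p under 0.05. The livers under 15 M reads were 902, 918, 977 and 984, so depth class cannot be told from other differences of these livers. In that fit 902 is the only control under 15 M reads and 910 the only BPA liver over it.

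Genes of protein synthesis, energy metabolism and protein turnover were lower in BPA livers as lists. All 75 tested cytosolic ribosomal protein genes had lower estimates (median -2.02 log2), 70 of them past the threshold adjusted over the list alone and 0 over all genes. RPS3 measured 1371 ± 521 in controls and 384 ± 491 in BPA, RPL26 701 ± 221 and 194 ± 239, and RPS4X 1283 ± 213 and 390 ± 412. Mitochondrial ribosomal proteins were at -0.52 (54 of 63 lower, 0 past adjusted over the list alone), with MRPS6 at 168 ± 29.8 and 64.0 ± 43.2, MRPL16 at 350 ± 109 and 155 ± 118, and MRPS10 at 356 ± 71.7 and 182 ± 145. Nuclear-encoded oxidative phosphorylation genes had a median of -1.45 (52 of 54 lower, 0 adjusted over the list alone), with the ATP synthase genes ATP5F1E (834 ± 363 and 253 ± 369) and ATP5PF (505 ± 141 and 200 ± 198) and the complex I gene NDUFA5 (70.6 ± 16.3 and 25.7 ± 20.9). The tricarboxylic acid cycle list was at -0.78 (25 of 26 lower, 0 adjusted over the list alone), citrate synthase CS being 521 ± 91.9 and 257 ± 67.9, with DLAT at 342 ± 101 and 189 ± 86.8 and SDHC at 1283 ± 742 and 422 ± 629. Glycolysis was at -1 (19 of 21 lower), with 6 lower and 1 higher (PFKFB1) adjusted over the list alone, among them PGAM1 (1115 ± 145 and 309 ± 368), ALDOA (1772 ± 115 and 786 ± 298) and PGK1 (970 ± 137 and 387 ± 259). Proteasome genes were at -0.80 (37 of 38 lower, 0 adjusted over the list alone), with PSMA4 at 328 ± 55.3 and 159 ± 112, PSMA7 at 552 ± 116 and 270 ± 178, and PSMD10 at 93.1 ± 7.22 and 50.1 ± 20.2. These 6 lists passed camera at the preset correlation, and none with an estimated correlation: adjusted p = 0.632 with an estimated correlation for the cytosolic ribosomal and glycolysis lists, 0.664 for oxidative phosphorylation, the tricarboxylic acid cycle and the proteasome, and 0.697 for mitochondrial ribosomal proteins. The BPA libraries 918, 977 and 984 had ribosomal protein medians of -1.55 to -2.06, and the BPA library 910 of 1.25. The BPA library 910 also lay above the other BPA livers for the tricarboxylic acid cycle (0.56), oxidative phosphorylation (0.92), mitochondrial ribosomal proteins (0.39), glycolysis (0.34) and the proteasome (0.44). The control 902 lay below the other controls for these (-0.87, -0.71, -0.58, 0.30 and -0.32), and for the first below every BPA liver.

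Stress and redox lists were lower as well, with single libraries standing apart. The BPA liver 910 lay near the controls for antioxidant defence (0.35, with -0.58 to -1.04 in the other BPA livers) and the unfolded protein response (0.42, with -0.58 to -0.86). For heat shock the BPA liver 918 was at 0.14, and for immediate early genes the BPA liver 977 was at 0.56 and the control 902 at 1.11, with -0.20 to 0.24 in the other controls. Antioxidant defence was at -0.79 (26 of 31 lower, 4 adjusted over the list alone: PRDX1, TXN, SRXN1 and GPX1). SRXN1, which reactivates peroxiredoxins, measured 309 ± 17.3 and 106 ± 72.9, thioredoxin TXN 375 ± 109 and 124 ± 123, and the glutathione peroxidase GPX1 958 ± 138 and 305 ± 382. The unfolded protein and integrated stress response was at -0.91 (21 of 26 lower, 0 adjusted over the list alone), with the chaperone CALR (6063 ± 1411 and 2651 ± 2913), MANF (531 ± 229 and 200 ± 178) and TRIB3 (297 ± 90.4 and 147 ± 52.5). Heat shock proteins were at -0.86 (16 of 20 lower, 0 adjusted over the list alone), with HSP90AB1 at 3561 ± 800 and 1552 ± 574, CRYAB at 295 ± 388 and 50.6 ± 28.9, and HSPB1 at 4852 ± 2365 and 1864 ± 1510. Immediate early genes were at -0.65 (24 of 25 lower, 0 adjusted over the list alone), with IER5 at 230 ± 182 and 82.2 ± 24.1, KLF6 at 916 ± 630 and 443 ± 126, and ATF3 at 224 ± 39.1 and 146 ± 74.9. Cholesterol synthesis was at -0.68 (19 of 23 lower, 0 adjusted over the list alone), with SQLE (298 ± 111 and 155 ± 64.7) and IDI1 (1144 ± 377 and 631 ± 228), the control 902 being lowest of the 8 livers (-0.77) and the BPA library 910 at 0.22. Imprinted genes were at -0.86 (17 of 21 lower, 0 adjusted over the list alone), with NDN (65.2 ± 15.5 and 23.2 ± 24.0), GNAS (2308 ± 290 and 1195 ± 717) and SGCE (150 ± 58.0 and 75.8 ± 37.0). For NDN (58.85), GNAS (2228) and SGCE (129.9) the BPA library 910 lay within the range of the controls. The cell cycle list was at -0.41 (27 of 38 lower, CDKN1A alone past adjusted over the list alone), with PCNA at 126 ± 30.0 and 62 ± 31.2 and CCND1 at 817 ± 92.3 and 428 ± 268. Without the control liver 902 the cell cycle median was -0.06 and its call was lost, as was that of immediate early genes. The cell cycle call was also lost without 910 and that of cholesterol synthesis without the control 928. The preset calls of these 7 lists were lost too: adjusted p = 0.632 with an estimated correlation for antioxidant defence, the unfolded protein response, heat shock and imprinted genes, 0.664 for immediate early genes and cholesterol synthesis, and 0.725 for the cell cycle.

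Markers of non-hepatocyte cells were also lower, and the extracellular matrix and fibroblast lists were highest in the control 902. All 17 macrophage and Kupffer cell markers had lower estimates (median -1.60), 11 past the threshold adjusted over the list alone, among them FCER1G (213 ± 49.95 and 51.9 ± 46.0), LAPTM5 (958 ± 178 and 276 ± 317) and the CSF1 receptor CSF1R (2071 ± 1008 and 660 ± 338). Endothelial markers were at -0.57 (15 of 19 lower, 4 adjusted over the list alone), with CLDN5 at 52.2 ± 14.7 and 14.02 ± 13.6 and PECAM1 at 742 ± 74.3 and 413 ± 70.0. The BPA library 910 lay below every control for FCER1G (120), LAPTM5 (749.7), CSF1R (1109) and PECAM1 (476.9), but not for CLDN5 (34.39). Extracellular matrix genes were at -1.19 (40 of 41 lower, 0 adjusted over the list alone), with the control 902 at 2.31, the other controls at 0 to 0.10, and the BPA library 910 at -0.11. MMP2 was at 342 ± 69.6 and 125 ± 76.8, TGFB1 at 462 ± 37.7 and 232 ± 118, and COL1A2 at 5548 ± 8901 and 473 ± 323, the control mean being set by 902 (18900, with 961 to 1357 in the others). Fibroblast and stellate markers were at -0.98 (16 of 20 lower, 0 adjusted over the list alone), with ECM1 at 1629 ± 542 and 662 ± 355, FBLN5 at 518 ± 125 and 252 ± 149, and FBLN1 at 1176 ± 2053 and 44.7 ± 26.2 (4255 in 902, with 98.1 to 219 in the other controls). Cholangiocyte markers were at -1.20 (13 of 14 lower, EPCAM and KRT19 past adjusted over the list alone), with EPCAM at 94.6 ± 87.6 and 9.51 ± 8.503, KRT19 at 286 ± 310 and 23.7 ± 13.01, and SOX4 at 181 ± 55.6 and 83.9 ± 39.3. For these 5 lists the preset call was lost, each with an adjusted p = 0.632 with an estimated correlation. The median fibroblast marker of the control 902, at 1.22, lay above that of every other liver.

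The 2 lists higher in BPA livers were chromatin enzymes and the core clock, with the highest medians in the libraries 977 (0.48 and 0.31) and 984 (0.54 and 0.67). The BPA library 910 (-0.29 and -0.13) lay within the range of the controls (-0.35 to 0.09 and -0.49 to -0.02), as did 918 for chromatin enzymes (0.03). Chromatin and DNA methylation enzymes had a median of 0.47 (48 of 55 higher, 0 adjusted over the list alone), with the deacetylases HDAC8 (83.3 ± 19.1 and 169 ± 81.8) and HDAC9 (23.6 ± 11.4 and 50.1 ± 18.9) and the demethylase KDM3A (527 ± 166 and 1120 ± 487). Core clock and output genes were at 0.40 (13 of 19 higher, 0 adjusted over the list alone), with ARNTL, which encodes BMAL1, at 274 ± 47.5 and 533 ± 147, and PER3 at 335 ± 153 and 1284 ± 815. Adjusted p = 0.664 with an estimated correlation for the first and 0.632 for the second. With the depth class as a covariate, chosen after seeing the data, 27 lists passed, 12 higher and 15 lower, against 2 and 18 without it. The calls of cholesterol synthesis, the tricarboxylic acid cycle, chromatin enzymes and mitochondrial ribosomal proteins were then lost. As the depth class separates 902, 918, 977 and 984 from the other livers, these changes are not an adjustment for depth alone. In all, 20 of 46 lists passed camera in liver, and 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.127, 11 lists at an unadjusted p under 0.05).

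The other liver lists did not pass. Their camera adjusted p at the preset correlation was 0.103 for mitochondrial biogenesis and dynamics (median 0.38) and for autophagy and lysosome (-0.19), 0.115 for skeletal muscle fibre markers (0.72), 0.138 for adipocyte markers (-0.74), and 0.142 for the spliceosome (0.30) and for smooth muscle markers (-0.44). It was 0.180 for neutrophil markers, 0.188 for acute phase, 0.231 for T and NK cell markers, 0.357 for fatty acid oxidation (-0.47), lipid uptake and lipoproteins (-0.28) and fast fibre sarcomere, and 0.420 for fatty acid synthesis (-0.24) and insulin and IGF signalling (-0.11). It was 0.435 for myogenesis, 0.518 for B and plasma cell markers, 0.529 for bile acid synthesis (-0.03), 0.716 for the urea cycle (-0.15), 0.817 for hepatocyte markers (-0.43) and 0.825 for gluconeogenesis (-0.10). It was 0.913 for complement and coagulation and for slow fibre sarcomere, 0.948 for xenobiotic metabolism (-0.13) and for steroid and nuclear receptors (-0.15), and 0.989 for the interferon response and nerve markers. Without the control 902, the lists of fatty acid oxidation, fatty acid synthesis, lipid uptake, bile acid, xenobiotic metabolism, urea cycle, complement, steroid receptors, hepatocyte, spliceosome, skeletal muscle fibre and T and NK cell markers passed. So did acute phase without the BPA library 910 and smooth muscle without the control 908. Erythroid markers had 2 tested members and were not tested as a list. Adjusted over the list alone, GRB14 and IGFBP5 (insulin and IGF signalling) and PMP22 (nerve) passed.

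None of the 17 liver panel genes given here passed. Fasting and insulin-axis genes lay within the spread: the carnitine transferase CPT1A measured 5123 ± 1957 in controls and 5619 ± 1257 in BPA, the gluconeogenic PCK1 21530 ± 5102 and 23520 ± 4887, and G6PC 4260 ± 2283 and 3647 ± 1313. INSR was 3190 ± 1135 and 3490 ± 641, IRS1 1242 ± 505 and 1551 ± 744, IRS2 670 ± 174 and 918 ± 436, IGF1 2015 ± 1204 and 1302 ± 1085, and IGFBP1 3698 ± 3382 and 5825 ± 4732. The control 902 widened the control spread of G6PC (844, with 5192 to 5599 in the other controls), INSR (1528, with 3402 to 3967) and IRS1 (509, with 1304 to 1580). In the BPA livers G6PC lay at 1951 to 4777. The desaturase SCD measured 690 ± 679 and 160 ± 20.05 (log2 -1.70, SE 0.505, adjusted p 0.256), FASN 708 ± 392 and 402 ± 184, and SREBF1 1221 ± 346 and 787 ± 77.5. The oestrogen receptor ESR1 was 2864 ± 823 and 1743 ± 843 (adjusted p 0.300), the glucocorticoid receptor NR3C1 1012 ± 391 and 1344 ± 487, and PPARA 3772 ± 1907 and 4730 ± 337. SOD2 (2433 ± 342 and 1193 ± 1317) and HMOX1 (969 ± 330 and 356 ± 274) had an adjusted p of 0.256, and the DNA methyltransferase DNMT1 (512 ± 146 and 543 ± 161) 0.914.

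**Figure D2:**
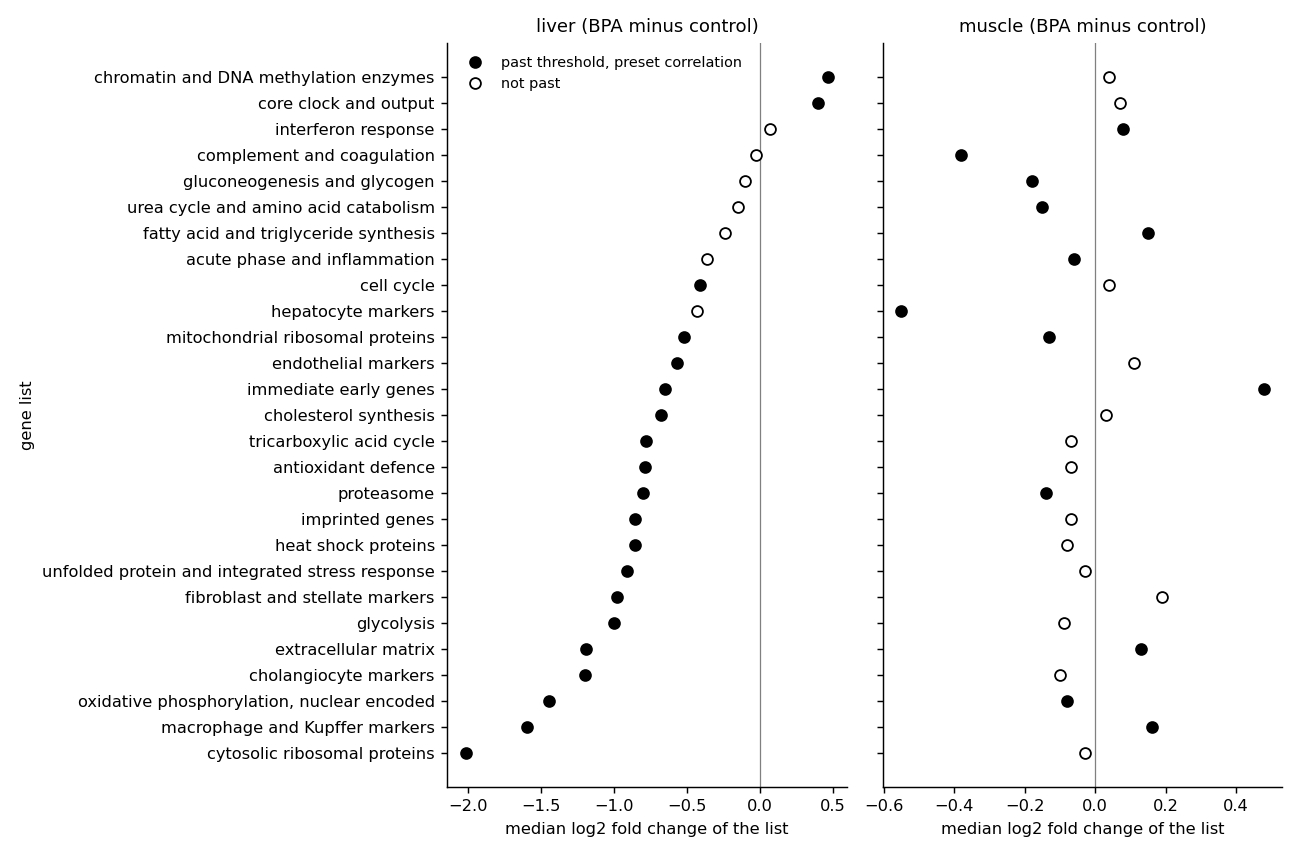
Median log2 fold change (x axis, BPA minus control) of each gene list (y axis) that passed camera at the preset correlation in at least 1 tissue, liver on the left and muscle on the right with different x scales. Filled points passed at the preset correlation, and 0 lists passed with an estimated correlation. Cytosolic ribosomal proteins were at -2.02 in liver, and hepatocyte markers at -0.55 in muscle.

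In muscle, the 3 fibrinogen chain genes, which are expressed mainly by hepatocytes, fell with prenatal BPA. FGA fell from 1633 ± 96.5 to 714 ± 108 (log2 -1.20, SE 0.106, adjusted p 0.000618), FGB from 2106 ± 168 to 837 ± 176 (-1.35, SE 0.130, adjusted p 0.000896) and FGG from 1277 ± 98.1 to 518 ± 93.4 (-1.31, SE 0.120, adjusted p 0.000741). Ceruloplasmin, CP, a copper-carrying plasma protein, fell from 347 ± 41.8 to 156 ± 46.0 (adjusted p 0.0331), the carbonic anhydrase CA12 from 379 ± 93.3 to 156 ± 24.3 (adjusted p 0.0251), and PABIR3 from 26.6 ± 5.48 to 7.01 ± 1.18 (adjusted p 0.0464). ARSD, an arylsulfatase gene, rose from 19.1 ± 9.22 to 95.6 ± 8.68 (log2 2.36, SE 0.263, adjusted p 0.00252), and FAM71A from 2.64 ± 0.423 to 17.8 ± 4.84 (adjusted p 0.0357). All 4 BPA libraries lay beyond all 4 controls for each. Means of the fibrinogen genes over the 8 livers were 78450 (FGA), 74110 (FGB) and 42560 (FGG), and the livers were unequal. The BPA liver 910 was highest (205300, 222200 and 116500) and the control 902 lowest (18350, 10560 and 8327). Among the BPA muscles 910 was also highest for these genes (872, 1099 and 652). Liver-type genes were those tested in muscle with a liver mean at least 20 times their muscle mean. By that definition their muscle mean is at most 5% of the liver mean, and the muscle libraries held the median liver-type gene at 0.938% to 1.96% of its liver level.

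The other 11 genes past the threshold carried only a LOC number, and all fell. They are named here because of their number and were not chosen by the rule. LOC101120204 (636 ± 29.6 to 135 ± 26.9, adjusted p 5.63e-05) and LOC105601867 (289 ± 34.7 to 77.4 ± 8.51, adjusted p 5.63e-05) both have HPS5 as a nearest named gene. LOC101102413 (1867 ± 167 to 732 ± 60.8, adjusted p 5.63e-05) lies between TXNL4B and DHODH. LOC101115576 (658 ± 60.3 to 310 ± 29.9), LOC101119509 (160 ± 34.1 to 52.8 ± 5.28) and LOC101116892 (531 ± 51.4 to 268 ± 55.0) lie between SERPINA5 and GSC, and reads shared between them were not excluded. LOC114117619 (361 ± 73.9 to 162 ± 28.4) lies between BPIFB4 and BPIFA3, and LOC101122347 (143 ± 53.7 to 15.7 ± 5.42) between TPH2 and TRHDE. For LOC101117146 (280 ± 31.4 to 142 ± 28.0), LOC101106374 (1088 ± 250 to 306 ± 78.1) and LOC101107772 (136 ± 93.6 to 1.71 ± 1.95) no neighbour is given here.

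Of 14706 muscle genes tested with limma, 19 passed, 2 higher and 17 lower in BPA, with 1142 at an unadjusted p under 0.05 against 735 from chance, and 3 of the 35 splits of the animals, the real one included, gave 1142 or more (highest 1241). With all 16 libraries in one fit limma called 0, with 188 at an unadjusted p under 0.05, and with sample quality weights 377. edgeR also called 19, 18 of them shared, and DESeq2 called 131 (42 higher, 89 lower). The BPA muscle library 984 lay closer to the mean of its 3 group partners (SD over genes 0.237 log2) than any other muscle library did (0.373 to 0.482). Genes high in 1 of those partners alone stood in 984 near the mean of the 3, and its independence as a replicate is not established. Without it 11 genes passed, all among the 19: FGA (adjusted p 0.00712), FGB (0.00788), FGG (0.00712), ARSD (0.0159) and 7 LOC genes. CA12 (0.106), CP (0.174) and PABIR3 (0.174) did not pass, and FAM71A was not tested. CA12, CP, PABIR3 and FAM71A also lost their calls when any of several other single libraries was left out: CA12 without 902, 924, 918 or 977, CP without any but 910, PABIR3 without any but 928, and FAM71A without any control. Without the BPA library 910, 31 genes passed, and of genes at 5% or more of their liver mean, a filter chosen after seeing the data, 4 passed, all lower. That filter leaves out the 11 liver-type genes among the 19 by construction.

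**Figure D3:**
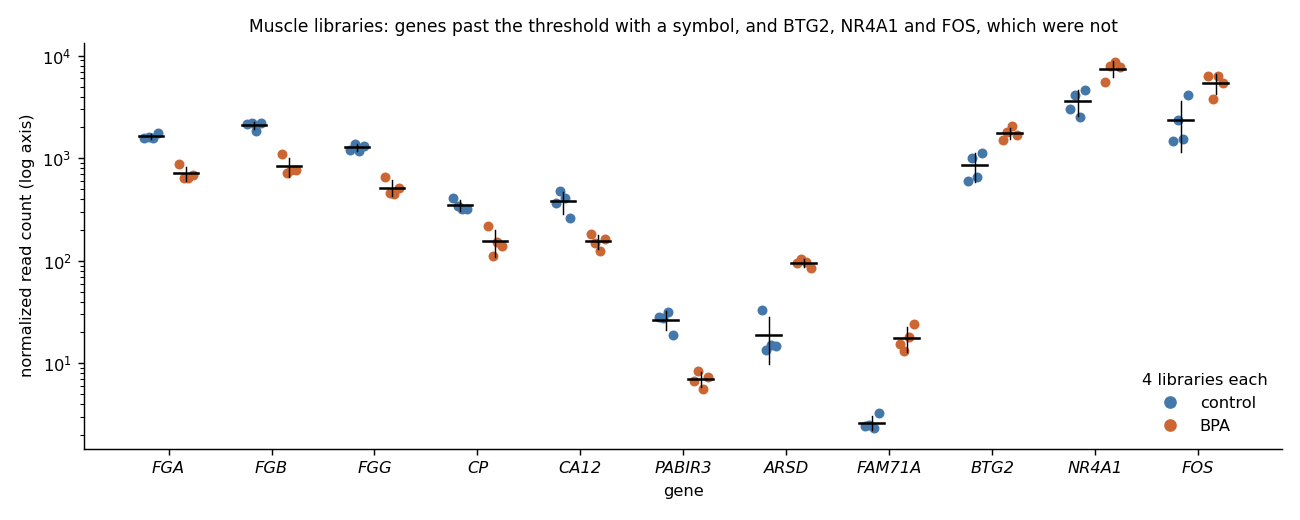
Normalized read counts (log axis) of 8 genes that passed the threshold in muscle and of BTG2, NR4A1 and FOS, which did not. Each point is 1 library (blue control, orange BPA), horizontal bars are means and vertical bars SD, n = 4. FGA lies at 1577 to 1777 in controls and at 640 to 872 in BPA.

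**Figure D4:**
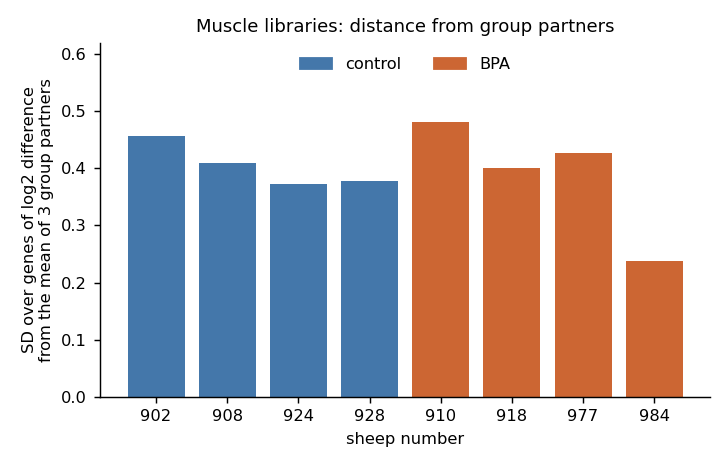
SD over genes of the log2 difference between each muscle library and the mean of its 3 group partners (y axis, bars from 0) by sheep number (x axis). The library 984 stands at 0.237 and the other 7 between 0.373 and 0.482.

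Among the muscle lists, hepatocyte markers, acute phase, complement, the urea cycle and gluconeogenesis were lower in BPA, with single libraries standing apart. The gluconeogenesis and glycogen list also holds muscle genes. The median hepatocyte marker was at 0.82 in the control 902 and -0.82 in the BPA library 918, and at 0.21 in the BPA library 910, above the 0.20, -0.04 and 0.06 of the other controls. Complement and coagulation was at 0.68 in 902, 0.31 in 910 and 0 to 0.13 in the other controls. All 19 hepatocyte markers had lower estimates (median -0.55), 3 past the threshold over all genes and 6 adjusted over the list alone (FGA, FGB, FGG, CPS1, APOB and TAT). Acute phase and inflammation had 4 lower over all genes (the fibrinogen genes and CP) and 8 adjusted over the list alone, with a median of -0.06. Complement and coagulation was at -0.38 (27 of 33 lower, 0 over all genes, 6 adjusted over the list alone), with C5 at 233 ± 30.2 and 118 ± 28.6 (adjusted p 0.0527, past without 910, as was C4BPA), C4BPA at 84.9 ± 11.2 and 41.9 ± 11.3, and plasminogen PLG at 271 ± 62.05 and 156 ± 42.8. The urea cycle list was at -0.15 (25 of 35 lower, 0 adjusted over the list alone), with CPS1 at 432 ± 95.5 and 260 ± 88.2, FAH at 220 ± 47.1 and 152 ± 21.9 and TAT at 36.6 ± 9.88 and 20.8 ± 5.25. Gluconeogenesis and glycogen was at -0.18 (17 of 23 lower, 0 adjusted over the list alone), with the muscle bisphosphatase FBP2 at 7144 ± 995 and 5311 ± 745 and G6PC at 42.1 ± 22.3 and 21.7 ± 9.60. All 5 passed camera at the preset correlation, and for each adjusted p = 0.717 with an estimated correlation. The gluconeogenesis call was lost without 902, 928 or 910, and that of the urea cycle without 902.

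Immediate early genes, which answer stimulation or tissue handling within minutes, were higher in BPA muscle (median 0.48, 20 of 24 higher). By library the list was at 0.27 to 0.34 in 3 BPA muscles and -0.09 in 918, and at -0.64 in the control 902 and -0.35 to 0.07 in the other controls. None passed over all genes, and 12 passed adjusted over the list alone, among them FOS, FOSB, JUN, JUNB, EGR1, ATF3, NR4A1 and BTG2. BTG2 measured 853 ± 262 and 1763 ± 223 (adjusted p 0.0697), NR4A1 3588 ± 1004 and 7510 ± 1349 (0.0805) and FOS 2377 ± 1234 and 5474 ± 1209 (0.180). The list passed camera, with an adjusted p = 0.717 with an estimated correlation. Without the control 928, BTG2, NR4A1, FOS and PRUNE2 passed over all genes, and NR4A1 also without the BPA library 910. PRUNE2, outside the list, measured 128 ± 33.9 and 248 ± 43.5 (adjusted p 0.113).

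Shifts were also seen in 7 further muscle lists. Mitochondrial ribosomal proteins were at -0.13 (51 of 63 lower), with MRPL27 at 246 ± 41.9 and 174 ± 18.9, MRPL54 at 249 ± 19.6 and 195 ± 22.7 and MRPL52 at 301 ± 18.5 and 245 ± 20.2. The proteasome was at -0.14 (35 of 38 lower), with PSMD4 at 2899 ± 228 and 2430 ± 294, PSMD5 at 270 ± 25.5 and 221 ± 30.4 and PSMC3 at 3011 ± 298 and 2487 ± 411. Oxidative phosphorylation was at -0.08 (48 of 54 lower), with NDUFS3 at 2125 ± 310 and 1690 ± 305, SDHD at 1667 ± 158 and 1430 ± 253 and ATP5PF at 1896 ± 294 and 1614 ± 389, and without the BPA library 910 its median was 0.02. Extracellular matrix was at 0.13 (37 of 41 higher), with COL15A1 at 1378 ± 141 and 1610 ± 114, COL4A1 at 3546 ± 244 and 4036 ± 198 and CCN2 at 166 ± 24.6 and 231 ± 71.2. Macrophage markers were at 0.16 (15 of 17 higher), with SPI1 at 43.4 ± 11.1 and 68.0 ± 18.0, LAPTM5 at 282 ± 18.4 and 357 ± 88.5 and CSF1R at 328 ± 48.2 and 426 ± 103. Fatty acid and triglyceride synthesis was at 0.15 (16 of 20 higher), FASN alone past adjusted over the list alone at 971 ± 35.2 and 1238 ± 45.8, with SREBF1 at 1697 ± 293 and 2193 ± 352 and FADS2 at 407 ± 40.0 and 464 ± 18.6. The interferon response was at 0.08 (23 of 31 higher), with IFI35 at 68.6 ± 6.83 and 96.6 ± 13.1, IFIT1 at 82.8 ± 5.49 and 105 ± 13.9 and STAT2 at 358 ± 4.09 and 409 ± 32.0. No member of these 7 passed over all genes, and 0 of the other 6 lists had a member past adjusted over the list alone. Adjusted p = 0.805 with an estimated correlation for oxidative phosphorylation and 0.717 for the other 6. Of these 7 calls, those of mitochondrial ribosomal proteins and the proteasome were lost without 910, extracellular matrix without 928 or 910, macrophage markers without 908, 928 or 910, and fatty acid synthesis without 918. Oxidative phosphorylation lost its call without 902, 928, 910 or 977, and the interferon response without 902, 908, 928, 910 or 918. In all, 13 of 45 lists passed camera in muscle (5 higher, 8 lower), 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.335, 3 lists at an unadjusted p under 0.05). Without the control 928, 8 lists passed, and without the BPA library 910, 7.

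The other muscle lists did not pass. The camera adjusted p at the preset correlation was 0.0782 for fibroblast markers (median 0.19), 0.0924 for the tricarboxylic acid cycle (-0.07), and 0.120 for fatty acid oxidation (-0.08), heat shock proteins (-0.08) and chromatin enzymes (0.04). It was 0.136 for mitochondrial biogenesis, 0.141 for adipocyte markers (0.11), 0.155 for cytosolic ribosomal proteins (-0.03), 0.167 for antioxidant defence and nerve markers, 0.171 for steroid and nuclear receptors, 0.226 for endothelial and cholangiocyte markers, 0.233 for the core clock, and 0.234 for insulin and IGF signalling (-0.08). It was 0.350 for smooth muscle markers, 0.395 for lipid uptake, 0.418 for imprinted genes, 0.419 for xenobiotic metabolism, 0.455 for fast fibre sarcomere (-0.06), 0.473 for glycolysis and skeletal muscle fibre markers, and 0.475 for the cell cycle and myogenesis. It was 0.571 for B cell markers, 0.577 for the spliceosome, 0.611 for the unfolded protein response, slow fibre sarcomere (0.05) and T and NK cell markers, 0.749 for bile acid synthesis, and 0.861 for cholesterol synthesis and autophagy. Calls were gained by fibroblast markers without 902, 924, 918 or 977, fatty acid oxidation and the tricarboxylic acid cycle without 924 or 918, heat shock without 902 or 918 and ribosomal proteins without 902 or 924. The same held for mitochondrial biogenesis without 918, slow fibre and adipocyte lists without 977, and nerve markers without 908 or 910. Neutrophil (3 tested) and erythroid markers (2 tested) were not tested as lists. Adjusted over the list alone, HSPB1 (heat shock), HSD17B12 (steroid enzymes) and HBB (erythroid) passed.

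None of the 17 muscle panel genes given here passed. Myostatin, MSTN, a brake on muscle growth, measured 269 ± 38.0 in controls and 186 ± 31.6 in BPA (log2 -0.53, SE 0.144, adjusted p 0.301). Glucose and insulin genes lay within the spread: the transporter SLC2A4 (1551 ± 308 and 1784 ± 628), INSR (2973 ± 406 and 2833 ± 197), IRS1 (2706 ± 236 and 3840 ± 1522) and HK2 (563 ± 174 and 495 ± 162). The same held for PDK4 (16550 ± 6187 and 16940 ± 4673), CPT1B (2847 ± 422 and 2519 ± 635), LPL (585 ± 120 and 610 ± 186), UCP3 (3420 ± 646 and 3160 ± 818), PPARGC1A (511 ± 118 and 551 ± 39.0) and PRKAA2 (1259 ± 152 and 1133 ± 196). Fibre genes MYH1 (1351000 ± 134100 and 1181000 ± 147500) and MYH2 (200400 ± 67310 and 242300 ± 83260), the atrophy ligase FBXO32 (28100 ± 2844 and 29660 ± 6007) and SOD2 (2823 ± 142 and 2707 ± 357) did not pass. The receptors ESR1 (922 ± 180 and 860 ± 150) and NR3C1 (2625 ± 134 and 2560 ± 79.4) had adjusted p of 0.913 and 0.933.

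The BPA effects in liver and in muscle were compared directly. The genes with the smallest p whose effect was higher in liver were the transcription factor ONECUT2 (log2 0.48 in liver and -1.21 in muscle), MAP2 (2.45 and -0.28), the albumin-family gene AFM (1.31 and -0.99), TMEM266 (1.42 and -0.36) and TTC39C (1.401 and -0.45). Those whose effect was lower in liver were LYVE1 (-2.66 and 0.65), MMRN1, an endothelial multimerin (-2.39 and 0.13), RDH11 (-1.33 and 0.28), PODXL (-1.99 and -0.08) and RAB27B (-1.23 and 0.82). Their adjusted p lay between 0.117 and 0.195. Of 13677 genes, 0 passed with limma (2661 at an unadjusted p under 0.05), 0 with edgeR (2932) and 148 with DESeq2. With the animal as a block limma called 0 (2296 at an unadjusted p under 0.05). Without animal 910, 3020 genes passed, the 10 named here among them, without animal 902, 4, and without animal 908, 1.

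Across the 13677 genes, which are not independent replicates, the BPA log2 fold changes in liver and muscle had a Pearson correlation of -0.0471 and a Spearman correlation of 0.00544. Of the 2522 genes at an unadjusted p under 0.05 in liver and the 1030 in muscle, 160 were shared, against 190 from independent lists, and 78 of the 160 had the same sign. Of the 35 splits of the animals, 17 gave a correlation as far from 0.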

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

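Of 286 groups of 4 values printed in the text or its panels, 36 held 1 library farther from its 3 partners than a critical ratio for 4 values allows (1 in 20 by chance), where 14 would be found by chance, and 16 of the 36 were in the control liver 902 and 8 in the BPA liver 910. In the control liver 902 these were recovered reads (4.39 M, units of 1e6), G6PC (844), INSR (1528), IRS1 (509), IDI1 (586), SDHC (205), RPL26 (373), MRPL16 (188), MRPS10 (251) and HDAC8 (54.6). The same library stood above its partners for SCD (1707), CRYAB (876), IER5 (503), KLF6 (1860), TGFB1 (518) and COL1A2 (18900). In the BPA liver 910 they were AFMID (1172) and HDAC9 (22.2), below its partners, and PGAM1 (860), ATP5F1E (807), TRIB3 (225), CALR (7016), MRPL16 (331) and IGF1 (2925), above them. In other livers they were KRT19 in 977 (4.99) and IRS2 in 918 (281). In control muscle they were ARSD (32.9), G6PC (75.5), CPS1 (575) and CPT1B (3476) in 902, FGB (1858) and SPI1 (59.8) in 924, FGA (1777) in 928 and FBXO32 (23870) in 908. In BPA muscle they were FAH in 918 (120) and STAT2 in 977 (456).

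The tests of fibrous tissue, of BPA as the whole cause, of liver material in muscle (a mixture, a lower share, the same animal), and both tests of the muscle library 984 were chosen after the result was seen. The control liver 902 and the BPA livers 918, 977 and 984 stood apart from 908, 924, 928 and 910. Lower depth does not account for it: after thinning to 4.39 M reads, the correlation among those 4 exceeded that with the others by 0.156, against 0.166 before. Fibrous tissue may account for 902, where the median fibroblast marker stood 1.22 log2 units above the mean of the livers (0.48 in the next), but not for 918, 977 and 984, where the highest was -0.56. The BPA liver 910 correlated better with the 3 controls than the control 902 did, by 0.279, but this restates how the pattern was seen and decides nothing about BPA. The unexposed 902 (0.01) also lay below 908, 924, 928 and 910 for ribosomal proteins, though less far than 918, 977 and 984 (-1.55 to -2.06). For 918, 977 and 984 BPA exposure and RNA quality remain open.

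Liver-type transcripts were present in every muscle library. Of the 14706 genes tested in muscle 495 were liver-type, as were 11 of the 19 past the threshold. Of these 11, 10 fell and ARSD rose. Reads or RNA from liver could account for their presence. Control muscle exceeded a fitted mixture of the livers by a median of 0.65 for the called genes (0.15 to 1.4). The SD of single liver-type genes around their fit was 0.91, which does not measure the spread of such a median. Of the called genes 10 were also picked for being higher in control than in BPA muscle, so this stays open. In BPA muscle ARSD lay 3.31 above the mixture, and the 10 that fell lay at -0.08 to 0.64. Whether a lower share of such material in BPA muscle is the whole cause of the 10 that fell cannot be decided. After each library's median liver-type deviation was subtracted, their median went from -1.20 to -0.93. At that smaller fold 10 stayed past the threshold adjusted over the 495 liver-type genes, and 6 adjusted over all genes (largest adjusted p with limma 0.206). The 10 were picked for falling in these same libraries, so their staying past was favoured in advance. The slope of each muscle library on its own liver library over the 495 genes was -0.144 to 0.088. RNA of the sequenced liver piece as the only source of these transcripts would give about 1, so that source is argued against. Material from another part of the same liver need not share what set these pieces apart, so the slopes do not decide on it. A mixture of livers and a true fall in muscle also stay open.

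The BPA muscle library 984 lay close to the mean of the other 3 BPA libraries. Genes high in 1 of those 3 alone stood in 984 at the level of the mean of the 3, with medians of 0.01 (27 genes from 910), 0.14 (2 genes from 918) and -0.14 (12 genes from 977), and the farthest from 0 was 0.14. The next library's was -1.2, and such a pattern could arise from material or reads of the other 3 in this library. Greater depth does not account for it: the 3 muscle libraries deeper than 984 had spreads of at least 1.59 times its own. No biological explanation was tested, and the BPA muscle group may hold fewer than 4 independent libraries.

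Splits of the animals or libraries showed which counts chance can produce. For muscle genes 1 of 35 splits, the real one with 19 genes, gave as many, and the highest other gave 4. If the muscle library 984 holds material of 910, 918 and 977, the real split is the only one that keeps these libraries together. It would then be favoured by construction, so chance cannot be excluded while the independence of 984 is not established. For liver genes and the difference between tissues the real count was 0, which all 35 of 35 splits match by construction, so these counts say nothing about chance. At an unadjusted p under 0.05 chance cannot be excluded in muscle, where the real split had 1142 genes, 3 of 35 splits had as many and the highest other had 1241. At that p the real split had 2838 genes in liver and 2661 for the difference, in each case with 2 of 35 splits as large, and the highest other had 6824 and 6007. That other split, 902, 918, 977 and 984 against the rest, gave 4892 and 4670 genes past the threshold and points to a structure of the samples. For lists chance cannot be excluded in liver (20 lists, 22 of 35 splits, highest other 27) or muscle (13 lists, 21 of 35, highest other 23). The same holds for the correlation between tissues (-0.0471, 17 of 35, highest other -0.186). For liver against muscle chance can be excluded over 100 splits (11420 genes, 1 split, highest other 9000).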

How the results depend on the processing

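Counts over liver genes were 0 in most settings, and moved to 2299 with all 16 libraries in one fit, 9588 with sample quality weights and 190 with DESeq2. Leaving out a library gave 0 to 2595. Liver lists past the threshold went from 20 to 0 with an estimated correlation and 0 with fry. Muscle genes went from 19 to 0 with all 16 libraries in one fit, to 377 with sample quality weights, to 131 with DESeq2 and, with a library left out, to 11 to 31. They went to 4 with only genes at 5% or more of their liver mean, a filter that leaves out the 11 liver-type genes among the 19 by construction. Muscle lists went from 13 to 0 with an estimated correlation, to 0 with fry, to 8 with that filter and to 7 to 17 with a library left out. The difference between tissues went from 0 to 148 with DESeq2 and 0 to 3020 with an animal left out. In the one fit over 16 libraries each gene has 1 residual variance for both tissues. The median SE was 0.44 log2 in liver alone and 0.15 in muscle alone. That fit thus tends to lower the SEs in liver and to raise them in muscle. The causes of the other changes were not tested.

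With the animal as a block, 0 genes passed for the difference between tissues, but in simulated data this fit recovered 0% of genes changed 4-fold, so that 0 says nothing about stability. The block moved the count of genes between tissues from 11420 to 11091. No paired analysis was possible within a tissue because each animal belongs to 1 group.

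The direction given by camera turned in these settings for the lists named, while the median itself did not always change sign. The depth class and both-shallowest settings were chosen after seeing the data. The depth class is the same split as 902, 918, 977 and 984 against the other livers. With the depth class as a covariate the medians were 0.52 for fatty acid oxidation, 0.56 for lipid uptake, 0.81 for the urea cycle, 0.41 for steroid receptors and 1.14 for hepatocyte markers in liver. With it 27 lists passed (12 higher, 15 lower), 16 of the 20 among them. With both shallowest livers left out 25 passed (2 higher, 23 lower), 17 of the 20 among them, and the medians were -0.6 for bile acid, -0.97 for xenobiotic metabolism, -0.78 for complement and 0.08 for the cell cycle. With a liver library left out, bile acid ranged from -0.68 to 0.35, xenobiotic metabolism from -0.87 to 0.17, complement from -0.74 to 0.19 and the cell cycle from -0.66 to -0.06. In muscle, oxidative phosphorylation ranged from -0.21 to 0.02, and the urea cycle was -0.01 with only genes at 5% or more of their liver mean. The cause was not tested. The 7 genes compared between tissues kept direction and call in all 98 values, and no named gene turned with a call. Depth limits low genes in the livers 902 and 918 (4.39 and 4.66 M reads).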

Other observations

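Haemoglobin and collagen transcripts varied between single libraries. HBB, the beta globin gene, measured 175, 19.95 and 8.42 in the muscle of the BPA sheep 910, 918 and 977, a mean of 67.8, and 68.1 in that of 984. It was 0.843 to 6.09 in the control muscles, and 83.3 in the liver of 910 with 0 in that of 984. COL1A1 was 43400 in the liver of the control 902 and 385 to 1956 in the other livers. LOC101120204 lay between 600 and 664 in the 4 control muscles, while it measured 245, 472, 1648 and 2874 in the livers of the same sheep.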
